A study of Rattus norvegicus with 12 samples.

How the data were processed

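Gene expression was measured in glomerular tissue of male SD rats, the tissue of the kidney's filtering units, on 12 one-colour Agilent rat 4x44K arrays. Per the labels, 4 arrays hold tissue from normal rats (control), 4 from rats of the experimental group (model, in a series on chronic glomerulonephritis) and 4 from rats given a treatment abbreviated TCM. The free-text description of every sample, TCM samples included, says that there was no treatment, so the groups were taken from the titles. Per the labels, total RNA was amplified and labelled with the dye Cy3. Per the file headers, the arrays share 1 design and were read with Agilent Feature Extraction 11.0.1.1, which is also the tool that the submitters' processing notes name, without a version.

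The deposited scanner files give, for each spot, a background-corrected signal as an intensity on a linear scale, as well as median intensities and quality flags. The authors also deposited 1 value table of the same arrays. Its values are on a log2 scale, judged from the deposited values themselves, and every column has the same median, 8.03. Each column followed the log2 signal of its own scanner file with a correlation of 0.9999 or more across probes. How the authors normalized that table is not given in the sources used here, so it served as an alternative.

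Each array held 42877 spots that are not controls, for 30367 probes. Log2 processed signals were set relative to the array's 75th percentile, which lay between 1533 and 1720 on the linear scale. Spots marked as outliers were set to missing, and spots of 1 probe were averaged. A probe counted as well above background on an array where over 0.5 of its spots carried that flag, and was tested if this held on every array of at least 1 group, which left 24389 probes. Between 77.5% and 83.9% of probes were well above background per array, and no spot was saturated. The number of arrays and dim signals limit the precision.

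Probes were named by matching their accession, without version, to a RefSeq gene table of assembly GRCr8, used for names alone because the array files name the older build rn4, so no coordinates are given. Of the 30367 probes, 18005 matched 15168 genes. Among tested probes 14926 matched 12588 genes and 9463 did not match. Where a gene had several probes, the brightest stood for it. Among the genes chosen by the rule given next, the probes of a gene differed by over 1 in log2 difference of model from control for Ces1a (1.79 and 5.05), Cd44 (0.60 to 2.22 over 4 probes) and Trpv5 (0.33 and 1.61). They differed in sign for Tal1, Rps16, Hsp90aa1, Ace and Nphs1.

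The 3 comparisons were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. A moderated F test asked whether the 3 groups differed. For 28 gene lists fixed before the data were examined, camera was run with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Named genes followed a rule fixed at the same time. It took up to 12 genes per direction and comparison with the largest difference among those past the threshold whose arrays did not overlap between groups, leaving out locus-number, predicted and olfactory receptor symbols. Where under 4 genes passed, it took the 5 higher and 5 lower genes with the smallest p. It added up to 4 members of each list, 14 anchor genes, and up to 10 genes changed in opposite directions in model against control and TCM against model, of which there were 0. Some genes that the rule takes are not reported here.

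Scan identifiers in the headers place the arrays on 3 slides of 4 arrays. Slide 1 holds model 1 and 2 with TCM 1 and 2, slide 2 the 4 control arrays, and slide 3 model 3 and 4 with TCM 3 and 4. To compare arrays with the noise of single spots, 1289 probes printed 10 times each and well above background on every array were used. For each pair of arrays, the squared difference of probe means was divided by its variance expected from the spread over spots, and the median was scaled so that 1 means spot noise alone. Because arrays of a slide and label differed by about the spot noise, they count as 1 sample in each mean and SD. Differences from control are thus given as the mean ± SD over the 2 slides (n = 2), and the control group gives 1 sample. Both slides are set against the same control mean, so this SD holds no spread between control samples. A TCM minus model difference is given with its 95% interval from a fit with slide as a block, which covers spread within slides.

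Whether replicate numbers pair the samples was checked with the correlation of deviations from the group means. It was between 0.70 and 0.80 for the 4 same-numbered pairs of model and TCM arrays, so these count as paired. It was as high, between 0.71 and 0.81, for the other number on the same slide, so the pairing comes from the slide. Pairs with control arrays reached -0.11 to 0.14 and do not count as paired.

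A probe not well above background on some or all arrays of a group has only a bound there, as was applied to the genes named by size. The brighter group's mean was set against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own, and the result is written as at least N-fold.

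The fit was tested on data simulated from the real means of 24318 probes without missing values, the spread within slides and added slide shifts. With changes of 1.5-fold, 2-fold and 4-fold in TCM against model, the fit with slide as a block recovered 91.0%, 97.0% and 100% of changed probes and the fit over all arrays 65.7%, 82.1% and 100%. For model against control the fit over all arrays recovered 62.7%, 83.6% and 97.0%. The added shifts were equal and opposite on slides 1 and 3 and absent on the control slide. A shift of the control slide, which cannot be told apart from the group, was thus not simulated. The spread within slides is that of repeated arrays, so these values are not the recovery over separate samples. With the larger spread of all arrays of a group, the fit with slide as a block recovered 59.7%, 85.1% and 93.9% for TCM against model. Unchanged groups were also simulated over 24389 probes, 100 times with independent arrays and 100 times with slide shifts drawn at the size of the difference between slides 1 and 3.

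Alternatives were normexp background correction (on the median signal, since the files hold no mean signal; offset 50), quantile and median scaling, 2 other filters on dim probes (without a filter, 30281 probes with values on every array), a floor on low signals, the deposited value table, other estimates of the spread, array weights, fits of 2 groups, replicate number or slide as a block, thresholds with at least 2-fold, a tubule score as a covariate, and each array left out. Slide means as samples, single slides against the control slide, and fry with slide as a random block were added after seeing the data.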

Results

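Glomerular gene expression was profiled in 3 groups of 4 arrays: normal rats (control), rats of a glomerulonephritis series' experimental group (model) and treated rats (TCM). The labels do not expand the abbreviation TCM. They do not say that the arrays of a group come from separate rats, so p-values measure the spread between arrays, which may be technical. Of 30367 probes, between 77.5% and 83.9% per array were well above background, and 24389 were tested.

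The arrays of 1 slide were nearly interchangeable. Over 1289 probes with 10 spots each, the variance of the difference between 2 arrays was at the median 1.05 times the spot noise for arrays of the same label on the same slide (10 pairs, 0.73 to 1.56). It was 1.09 times the spot noise for a model and a TCM array on the same slide (8 pairs, 0.43 to 2.09). Arrays of the same label on different slides differed by 96.5 times the spot noise (8 pairs, 93.0 to 103). Arrays of a slide and label therefore differed by about the measurement noise and were counted as 1 sample, which leaves at most 2 model samples, 2 TCM samples and 1 control sample. By the same measure, model and TCM arrays of a slide also differed by about the measurement noise, so it is not known whether they hold separate RNA samples. All 4 control arrays share slide 2, which holds no other group, so slide and group cannot be told apart in either comparison with control. The first principal component, with 72.9% of the variance, separated the control slide from the others, and the second, with 18.2%, separated slide 1 from slide 3.

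**Figure D1:**
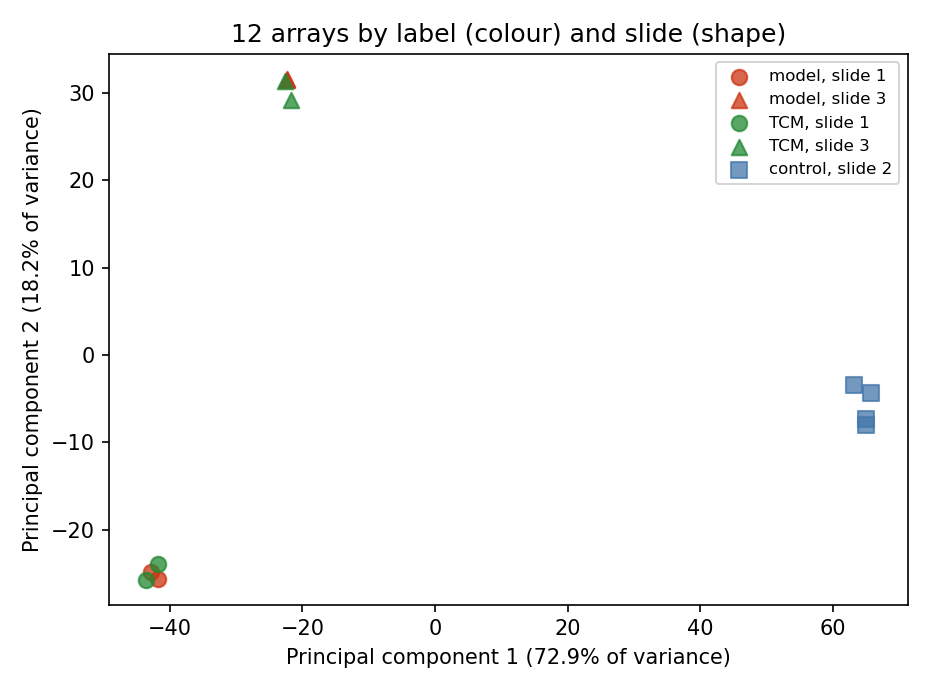
Each point is 1 of the 12 arrays, placed by its scores on the first 2 principal components of the tested probes (arbitrary units, with 72.9% and 18.2% of the variance). Colour gives the label and shape the slide, and model and TCM arrays of a slide lie together.

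The comparison of model with control asks which transcripts differ between the experimental group and normal glomerular tissue. Model arrays had far more Havcr1, the tubular injury marker KIM-1, with a log2 difference of 4.34 ± 0.54 (SD, n = 2 slides). Such an SD, here and below, leaves out any spread between control samples. Among gene lists, T and NK cell genes (adjusted p = 0.012 with an estimated correlation), chemokine, cytokine and adhesion genes (adjusted p = 0.011) and complement and coagulation genes (adjusted p = 0.040) were higher in the model arrays. Interferon-response genes were lower (adjusted p = 0.011 with an estimated correlation). These list p-values are from camera with every array counted as a sample, so they do not measure the spread between samples. The pan-leukocyte gene Ptprc was higher by 0.94 ± 0.04 and the matrix protein gene Fn1 by 0.74 ± 0.28. The brush-border peptidase gene Anpep differed by -1.79 ± 0.02.

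In limma over the 12 arrays, 8766 probes were higher and 6205 lower in model than in control at an adjusted p of 0.05. Together they were 61.4% of those tested. Quantile scaling gave 7105 higher and 7480 lower, so the excess of higher calls depends on the scaling. These calls rest on arrays that repeat each other within a slide. With slide as a random block, 4225 probes were higher and 3619 lower, and with slide means as samples 0 passed (4802 at an unadjusted p under 0.05). Slide means with a robust, trended spread gave 825 calls. Both fits of slide means take the spread from the 2 model slides alone and assume that the 1 control sample varies like them, so neither count measures the spread between control samples. The random block assumes 1 correlation within slides, 0.80, for all probes. With 1 control slide, its counts do not measure that spread either. By size alone, 987 probes were at least 2-fold higher and 444 at least 2-fold lower than control on both slides, and 9 moved in opposite directions.

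The 12 named genes with the largest increases included 9 that were not well above background on any control array. Vegfb (NM_053549), a vascular growth factor gene with 1 tested probe, was at least 69.8-fold higher. Atp12a (NM_133517), a proton pump gene, was at least 29.8-fold higher and Prss22, a serine protease gene, at least 28.1-fold. Klra1 was at least 18.6-fold higher, Alox15b at least 15.2-fold, Ces1a at least 9.95-fold (at least 2.95-fold by its other probe), Reg3b at least 7.05-fold and Fosl1 at least 5.56-fold. C4bpa was at least 8.30-fold higher over both slides, at least 3.95-fold on slide 1 and at least 17.45-fold on slide 3. Angptl4 (NM_199115), an inhibitor of lipoprotein lipase, was measured on all arrays and was higher by 5.44 ± 0.23 on the log2 scale. Il24 and Dio3 were well above background on 1 of 4 control arrays each and were at least 42.5-fold and at least 22.6-fold higher.

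Among the largest decreases, the interferon-induced gene Ifit1 was well above background on the 2 model arrays of slide 3, where it differed by -4.91, and not on the 2 of slide 1, where it was at least 43.5-fold lower. The xenobiotic-metabolising gene Cyp1a1 differed by -6.04 ± 1.31 (-5.11 on slide 1 and -6.96 on slide 3), Cyp2c11 by -4.17 ± 0.24, Ugt2b7 by -3.96 ± 0.59 and Spata22 by -3.96 ± 0.93 (-4.61 and -3.30). Isg15 differed by -3.01 ± 0.10, Scgb1c1 by -3.19 ± 0.19 and Anxa13 by -3.03 ± 0.18. Nmbr was at least 5.94-fold lower, Atp1a4 at least 2.44-fold, Zp2 at least 2.35-fold and Adh7 at least 2.12-fold, all below background in the model arrays. The 24 genes named by size were chosen from the same data for their large differences, so passing again is no independent support. All 24 of these genes stayed past the threshold with slide as a random block, and 0 did with plain slide means. With slide means and a robust, trended spread 22 did, all but Ifit1 and Zp2, where the 2 model slides alone gave the spread.

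Counts of list members are over all genes tested, with the counts adjusted over the list alone beside them where they differ. Of 28 lists, camera called 20 at an adjusted p of 0.05, 12 higher and 8 lower in model, and 4 of these held with an estimated correlation: T and NK cell genes, chemokines and cytokines, complement and coagulation, and interferon response. Fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, called 25 lists, and 26 with slide as a random block. Camera, and fry without a block, count the 12 arrays as separate samples, though arrays repeat each other within a slide. Their p-values therefore do not measure the spread between samples. Fry with the random block assumes 1 correlation within slides for all genes. The 1 control slide gives it no spread between control samples. All the list tests use the same arrays and so carry the same confounding with slide, and some lists share members.

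Of 23 kidney injury genes, 19 were higher and 1 lower (median log2 difference 1.09; camera adjusted p = 7.85e-06, adjusted p = 0.12 with an estimated correlation). They include the adhesion receptor gene Cd44 (2.22 ± 0.15), Krt18 (1.69 ± 0.14) and S100a6 (1.48 ± 0.14). Of 23 macrophage and monocyte genes, 20 were higher and 0 lower (median 0.67; camera adjusted p = 3.69e-06, adjusted p = 0.078 with an estimated correlation), among them Itgam (1.39 ± 0.11), Cd68 (0.61 ± 0.08) and Tyrobp (0.67 ± 0.05). Of 22 T and NK cell genes, 18 were higher and 2 lower (median 0.65; camera adjusted p = 7.56e-05, adjusted p = 0.012 with an estimated correlation), or 19 and 2 adjusted over the list alone. They include the T cell receptor complex gene Cd3g (0.92 ± 0.00). Of 43 chemokine, cytokine and adhesion genes, 30 were higher and 3 lower (median 0.54; camera adjusted p = 9.91e-05, adjusted p = 0.011 with an estimated correlation), with Icam1 at 1.23 ± 0.03 and Ccl2 at 1.62 ± 0.13. Of 36 complement and coagulation genes, 20 were higher and 5 lower (median 0.46; camera adjusted p = 0.0047, adjusted p = 0.040 with an estimated correlation), with the fibrinogen gene Fgb at 4.58 ± 0.12 and C6 at 2.00 ± 0.06. MHC class II genes were higher for 9 of 13 and lower for 0 (median 0.50; camera adjusted p = 0.0057, adjusted p = 0.056 with an estimated correlation), with RT1-Da at 0.53 ± 0.01.

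Of 35 extracellular matrix genes, 27 were higher and 4 lower (median 0.58; camera adjusted p = 0.00039, adjusted p = 0.42 with an estimated correlation). Timp1 was higher by 1.68 ± 0.24 and Mmp14 by 1.14 ± 0.10, while Tgfbi differed by -0.95 ± 0.05 and Col1a1 by -0.18 ± 0.12. Of 35 immediate early and heat shock genes, 20 were higher and 3 lower (median 0.71; camera adjusted p = 0.0054, adjusted p = 0.28 with an estimated correlation), with Nr4a3 at 1.37 ± 0.15. Of 34 apoptosis genes, 21 were higher and 5 lower (median 0.31; camera adjusted p = 0.0057, adjusted p = 0.24 with an estimated correlation), with Bik at 1.89 ± 0.17. Of 70 ribosomal protein genes, 44 were higher and 1 lower (median 0.24; camera adjusted p = 8.86e-05, adjusted p = 0.49 with an estimated correlation), or 45 and 1 adjusted over the list alone. Rpl12 was higher by 0.43 ± 0.00.

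Lists that were lower began with the interferon response, where 23 of 36 genes were lower and 6 higher (median -0.51; camera adjusted p = 4.77e-05, adjusted p = 0.011 with an estimated correlation), with Ifit2 at -1.64 ± 0.05 and Oas1a at -2.08 ± 0.16. Of 51 oxidative phosphorylation genes, 49 were lower and 0 higher (median -0.44; camera adjusted p = 1.74e-12, adjusted p = 0.15 with an estimated correlation), with Cycs at -0.77 ± 0.02. Of 31 proximal tubule genes, 24 were lower and 1 higher (median -0.48; camera adjusted p = 3.23e-05, adjusted p = 0.25 with an estimated correlation), with Ggt1 at -0.84 ± 0.05 and Slc22a12 at -1.31 ± 0.25, while Slc13a1 was higher by 0.82 ± 0.10. Of 33 genes in the oxidative stress defence list, 18 were lower and 7 higher (median -0.41). The camera adjusted p was 0.0052, and 0.25 with an estimated correlation. This list also holds oxidase genes, among them Nox4 at -1.73 ± 0.02, which produces oxidants and is not itself a defence gene. Renin-angiotensin genes were lower for 9 of 13 and higher for 3 (median -0.35; camera adjusted p = 0.011, adjusted p = 0.073 with an estimated correlation), with Mme at -1.44 ± 0.04. Fatty acid oxidation genes were lower for 15 of 33 and higher for 7 (median -0.24; camera adjusted p = 0.035, adjusted p = 0.45 with an estimated correlation), or 17 and 7 adjusted over the list alone. Red cell genes were lower for 7 of 8 (median -0.99; camera adjusted p = 0.0013, adjusted p = 0.056 with an estimated correlation), with Alas2 at -1.33 ± 0.14. Adrenal cortex genes were lower for 4 of 5 (median -0.97; camera adjusted p = 0.033, adjusted p = 0.12 with an estimated correlation), while Cyp11a1, which did not pass, was at 0.69 on slide 1 and -2.64 on slide 3.

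Podocyte genes differed in level between the slides. Of 24 podocyte genes, 12 were higher and 1 lower (median 0.33; camera adjusted p = 0.033, adjusted p = 0.49 with an estimated correlation), or 11 and 1 adjusted over the list alone, with a median of 0.13 on slide 1 and 0.52 on slide 3. The slit diaphragm gene Nphs1 was at -0.55 on slide 1 and 0.46 on slide 3, and did not pass (adjusted p = 0.91 in limma). Wt1 was at 0.30 on slide 1 and 1.22 on slide 3. Cdkn1c was higher by 1.02 ± 0.09. Parietal epithelium genes were higher for 8 of 12 and lower for 1 (median 0.61; camera adjusted p = 0.035, adjusted p = 0.15 with an estimated correlation), with Cldn1 at 1.36 ± 0.10.

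The other 8 lists did not pass camera (adjusted p from 0.053 to 0.93). Mesangial and mural genes were higher for 10 of 20 and lower for 3 (median 0.29; 10 and 4 adjusted over the list alone), with Des at 1.35 ± 0.13 and Pdgfrb at 0.49 ± 0.17, while Acta2 was at -0.12 ± 0.08 and did not pass. Glomerular endothelium genes were higher for 11 of 21 and lower for 3 (median 0.19), with Plat at 0.75 ± 0.02, Pecam1 at 0.45 ± 0.10 and Ehd3 at 0.46 ± 0.14. B and plasma cell genes were higher for 7 of 11 and lower for 2 (median 0.94; 8 and 2 adjusted over the list alone). Distal nephron genes were higher for 6 of 23 and lower for 4 (5 and 4 adjusted over the list alone). Their median, 0.12, and mean, -0.04, differ in sign, and camera's direction is that of the median. Neutrophil genes were higher for 3 of 13 and lower for 3, with a median of -0.14 and camera's direction lower while the mean was 0.28. Adipocyte genes were higher for 6 of 12 and lower for 2 (median 0.22), and cell cycle genes higher for 5 of 38 and lower for 8 (median -0.05). Reference genes were lower for 7 of 14 and higher for 0 (median -0.09), with Gapdh at -0.34 ± 0.03. The tubular genes Slc34a1 (-0.06 ± 0.15) and Umod (-0.18 ± 0.14) did not pass. In limma with slide as a random block, Gapdh (adjusted p = 0.069), Pecam1 (adjusted p = 0.078) and Col1a1 (adjusted p = 0.22) no longer passed.

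**Figure D2:**
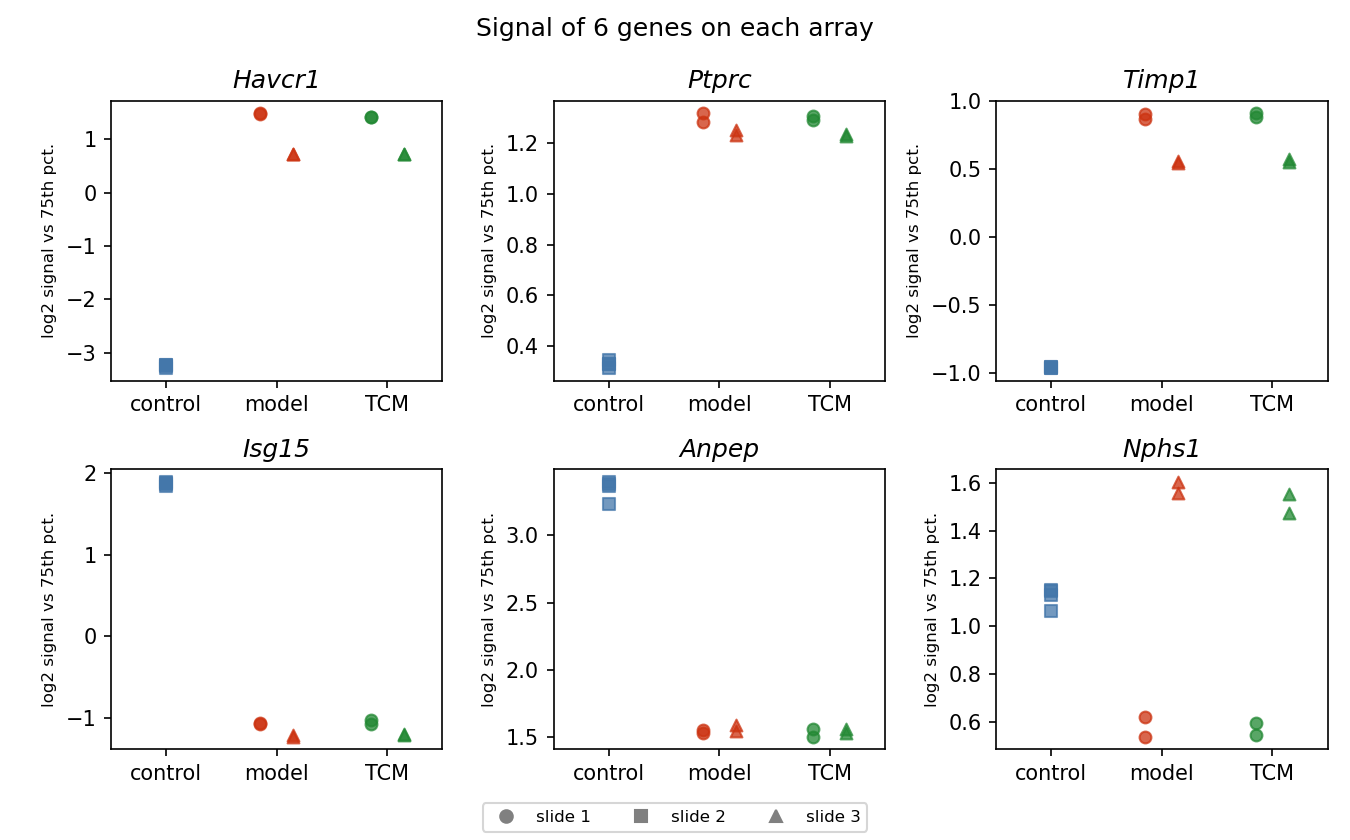
Log2 signal of 6 genes relative to the array's 75th percentile (vertical axes), with 1 point per array, columns and colours for the labels and shapes for the slides. Model and TCM arrays of 1 slide overlap, Havcr1, Ptprc and Timp1 lie above control, Isg15 and Anpep below, and Nphs1 lies on either side of control by slide.

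The comparison of TCM with model asks what differed in treated rats. Differences between the labels were within the spread of the arrays for the injury, leukocyte, matrix, interferon and podocyte genes given next. Havcr1 differed by -0.03 on the log2 scale (95% interval -0.08 to 0.02, with slide as a block), Ptprc by 0.00 (-0.05 to 0.04), Fn1 by 0.01 (-0.06 to 0.07), Isg15 by 0.02 (-0.03 to 0.06) and Nphs1 by -0.04 (-0.11 to 0.04). In limma 0 of 24389 probes passed over all arrays (183 at an unadjusted p under 0.05). With slide as a block 0 passed (1335 at an unadjusted p under 0.05, or 5.47% of probes), and 0 passed within slide 1 (1832 unadjusted) or within slide 3 (1529 unadjusted). The interval lay within 1.5-fold for 97.7% of probes. These intervals cover the spread between arrays of a slide, which was that of the spots. Because model and TCM arrays of a slide differed by 1.09 times the spot noise, these counts and intervals do not bear on the treatment if the arrays of a slide hold 1 RNA sample.

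The 5 genes with the smallest p in each direction did not pass. P2ry4 was at 0.29 (0.13 to 0.44), Astl at 0.31 (0.15 to 0.47), Ttc9b at 0.36 (0.07 to 0.65), Prm1 at 0.22 (0.05 to 0.38) and Limk2 at 0.11 (0.04 to 0.17). Ccr7 was at -0.29 (-0.49 to -0.10), Syngr4 at -0.43 (-0.71 to -0.15) with 1 of 4 TCM arrays well above background, Wdr13 at -0.10 (-0.14 to -0.05), Rnase1 at -0.15 (-0.25 to -0.05) and Wnt7a at -0.29 (-0.45 to -0.13). None of the 28 lists passed camera (smallest adjusted p = 0.99), fry or fry with slide as a random block.

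The comparison of TCM with control asks how far treated rats remained from normal rats. It gave nearly the values of model against control. Havcr1 was higher by 4.31 ± 0.49, Ptprc by 0.93 ± 0.05 and Angptl4 by 5.45 ± 0.21, while Cyp1a1 differed by -6.06 ± 1.29. Vegfb was at least 68.6-fold higher. The 12 largest increases were the 12 genes named for model against control, and 10 of the 12 largest decreases were shared, with Rbp4 and Mlc1 (-3.12 ± 0.88) in place of Zp2 and Anxa13.

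In limma 8658 probes were higher and 6220 lower, 7878 in all with slide as a random block and 0 with slide means (5168 at an unadjusted p under 0.05). Camera called 21 of the lists, 3 of them with an estimated correlation, while fry called 25, and 26 with slide as a random block. In both comparisons 8263 probes were higher and 5932 lower, where independent lists would share 3112 and 1583, and 0 were called in opposite directions. The 2 sets of differences had a correlation of 0.99 across probes and a covariance of 0.380. Unchanged simulated groups that share controls gave 0.50 and 0.011 with independent arrays, and 0.97 and 0.112 with slide shifts of the size seen between slides 1 and 3. With the control arrays split the correlation was at least 0.96. Since the controls and the slides are shared, this is no independent repeat.

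The F test over the 3 groups found 14379 probes. The return of model changes under TCM was then counted: 0 probes were changed in opposite directions in model against control and TCM against model, and 0 in the same direction. Both counts were bound to be 0, since 0 probes passed in TCM against model, so they add nothing to that result. The correlation of the 2 sets of differences was -0.05 and their covariance -0.0029. Simulated unchanged groups that share the model arrays gave -0.50 and -0.011 with independent arrays, which these were not. With the slide shifts the correlation was -0.13 (-0.16 to -0.09 over 100 simulations) and the covariance -0.0036 (-0.0047 to -0.0025), so the observed covariance lay within the range and the correlation outside it. With the model arrays split so that none was in both comparisons and each set held both slides, it was between -0.02 and 0.01.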

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

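The comparisons with other splits of the arrays were planned before the data were examined. The tests on slides and on liver transcripts were chosen after the results were seen. Of 204 groups of 4 arrays looked at, 6 had 1 array apart from the others, and chance alone marks about 1 in 20. That rate assumes 4 independent arrays. Model and TCM arrays lie evenly on slides 1 and 3, and where these slides differ a lone array apart is less likely.

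In the control group, Ces1a was at -7.08 on array 4 against -8.41 to -8.26 on the others, all below background. Cyp1a1 was at 1.89 on control 4 against 1.87 on the others, and Ehd3 at -2.97 on control 2 against -3.01 as the lowest of the others. Cd68 was at -0.26 on control 1, where the others equal it to 2 decimals. The mean of the mesangial and mural list was -0.99 on control 3 against -0.81 to -0.78. The 75th percentile signal of model 2 was 1590 against 1676 to 1689 on the other model arrays.

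For model against control, 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many as 14971 changed probes, and the highest other gave 0. For TCM against control it was also 1 of 35, with 14878 probes and 0 for the highest other. The arrays of a slide and label repeat each other within spot noise, so splits that mix them are bound to give few calls, and the samples are too few for a share under 0.05. The real split in both is also the split by slide. For TCM against model all 35 splits gave at least the 0 probes of the real one. The highest other, 16700 probes, parts slide 1 from slide 3, which shows a structure of the arrays that the labels do not follow, and with slide as a block the real split gave 0. The other splits that part all 4 pairs of equal numbers gave 0.

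Arrays of a slide were alike whatever their label. Hybridization or scanning of the slide is argued against as the whole cause, because 2 probes of a gene shared their difference between slides 1 and 3 with a correlation of 0.53 across 2145 genes (at most 0.056 in shuffled pairings), though probe sequences were not compared and labelling or amplification per slide stays open. One RNA preparation shared by the arrays of a slide stays open: the ratio of 1.09 for model against TCM arrays of a slide is the pattern itself, so it cannot bear this out. Rats that differ little from each other also stay open: arrays of 1 label on different slides differed by 96.5 times the spot noise, but processing per slide could add that difference. Whether any label is out of place was not tested, and a TCM effect too small to see here is an untested biological explanation.

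The probes called in model against control may owe an unknown part to the slide. Slides 1 and 3, which hold the same 2 labels, differed in 16667 probes in a fit with label and slide. With the slide difference likewise out of the spread, model against control gave 18389 probes for slide 1 and 18036 for slide 3. All control arrays lie on a slide of their own, so slide and disease cannot be told apart, and the disease stays an open, untested explanation. In size the control slide stood further off: 2622 and 1849 probes differed at least 2-fold between the model arrays of slides 1 and 3 and control, against 647 between the model arrays of the 2 slides.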

How the results depend on the processing

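Slide means, single slides and fry with the slide block were added after seeing the data. The counts for model against control, TCM against control and the 3 groups stayed within 1.5 times under all other scalings, backgrounds, filters, value tables, spread estimates and covariates tried; each array left out gave 13881 to 15133 and 13749 to 14967 for the first 2. With slide as a random block 7844 and 7878 probes passed, with slide means 0 and 0, and with slide means and a robust, trended spread 825 and 1058. Fits of slide means hold 3 samples, 1 of them control, which is assumed to vary like the others; for the random block and for the gap between the 2 fits of slide means the cause was not tested. Requiring 2-fold left 1993 and 1996 (adjusted p) or 1999 and 2006 (unadjusted), by construction. TCM against model gave 0 except 2 probes at unadjusted p with 2-fold and 6 with slide 1 and the control slide alone; return of model changes gave 1 and 5 there. Chosen after their values were seen, the 2 were Fut1 (-1.16), which is also the 1 that returned, and an olfactory receptor, and the named ones of the 5 were Fndc7 (0.60) and an olfactory receptor. With the replicate block, 16050, 0 and 15924 probes passed, and no count moved by over 1.5 times. This block also joins control arrays to the others by number, though these do not count as paired. Among named genes the random slide block ended 37 calls in model against control and 40 in TCM against control. The replicate block added 7 calls in model against control, and added 2 and ended 4 in TCM against control. The share of calls that were higher in model was 58.6%, against 48.7% with quantile scaling, 49.1% with median centring and 52.5% with normexp; for TCM against control it was 58.2%, against 49.0%, 49.0% and 54.5%. Lists called fell from 20 to 4 (model against control) and from 21 to 3 (TCM against control) with an estimated correlation, while fry called 25 in both, and 26 with slide as a random block.

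Directions turned in few cases, and the cause was not tested. In model against control, Prm1 was at -0.045 with quantile scaling and -0.045 with the deposited table, and Slc7a11 at -0.021 with that table. In TCM against control, Limk2 was at -0.18 with both. With the tubule score, model against control gave Cd4 -0.013, Cdc20 0.38, Rpl27 -0.0028 and Nphs1 1.11, and TCM against control gave Lyz2 -0.13, Cd79b -0.39, Elane -1.55, Rrm2 0.030, Acadl -0.18, Nphs1 1.06 and a fatty acid oxidation median of 0.015. With slide 1 and control alone, Elane was at 0.61 and Cyp11a1 at 0.69 in model and 0.62 in TCM, and Osm in TCM at -0.15. With slide 3 and control alone, Nphs1 was at 0.46 in model and 0.39 in TCM. Dim signals limit the genes named by size in model against control that were below background on any array of a group, which have bounds there.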

Other observations

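The tests here were chosen after the result was seen. Slides 1 and 3 hold the same 2 labels, yet differed in genes that the comparisons above average over. Podocyte genes were higher on slide 3 for 19 of 24 and on slide 1 for 3 (median log2 difference, slide 3 minus slide 1, 0.41), proximal tubule genes for 23 and 6 of 31 (median 0.34), distal nephron genes for 14 and 8 of 23 (median 0.27), cell cycle genes for 25 and 7 of 38 (median 0.21) and fatty acid oxidation genes for 20 and 6 of 33 (median 0.18). On slide 1, with the number higher on slide 3 second, ribosomal protein genes were higher for 51 and 0 of 70 (median -0.16), extracellular matrix genes for 28 and 4 of 35 (median -0.33), immediate early and heat shock genes for 23 and 6 of 35 (median -0.35), B and plasma cell genes for 9 and 2 of 11 (median -0.52), kidney injury genes for 17 and 6 of 23 (median -0.28), adrenal cortex genes for 3 and 2 of 5 (median -0.27), red cell genes for 5 and 1 of 8 (median -0.22), macrophage and monocyte genes for 16 and 6 of 23 (median -0.19) and parietal epithelium genes for 7 and 4 of 12 (median -0.16). The other 14 lists had medians from -0.14 to 0.14. These counts are from limma with label and slide in the fit. Each slide and label is 1 sample, so they compare these samples and not conditions.

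Single genes, chosen after their values were seen, differed alike under both labels. Vtn was higher on slide 3 by 4.01 in the model arrays and 3.97 in the TCM arrays, and Cyp3a18 by 3.64 and 3.71. Fos differed by -2.32 and -2.37, Lcn2 by -2.17 and -2.28 and Pnoc by -3.48 and -3.60.

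Several of the genes higher on slide 3 are abundant in liver, which raised the hypothesis of liver RNA in those arrays. A list of 43 hepatocyte genes that left out those already noticed had 30 tested members, 6 of them also expressed in kidney. Of the 30, 26 were higher on slide 3, with a median of 0.63, above all of 10000 random lists matched on expression (highest 0.28). Against it, 4 members were lower on slide 3 past the threshold (Arg1, Tf, Fga and Kng1, the last by -0.73), so the list leaves liver RNA open. Levels of abundant liver transcripts on slide 3 were -3.95 for Ahsg, -4.35 for Serpina1 and -1.69 for Apob. These are log2 values relative to the 75th percentile in the model arrays. Relative to control, these 3 genes were lower on slide 1 (-0.11, -0.19 and -0.48) and higher on slide 3 (0.66, 0.75 and 0.43). Gc was below control on both slides (-2.95 and -1.98). More proximal tubule on slide 3 may be another source. The 24 members not known from kidney exceeded the proximal tubule list by 0.31 (two-sided permutation p = 0.021), but by 0.22 (two-sided permutation p = 0.085) without 5 members that were brighter than the 75th percentile in control, so this stays open too.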
